A study of Arabidopsis thaliana with 27 samples.

How the data were processed

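The labels describe whole Col-0 seedlings grown for 10 days at 17 °C in long days, RNA taken from 30 mg of tissue, and paired reads of 100 bases from a HiSeq2000. Per the labels, 2 library kits (a stranded and an unstranded one) and 2 sequencing centres were used, without saying which library got which. Per the submitters' processing notes, FastQC, Trimmomatic, TopHat and Picard were used with the TAIR10 build. Versions, settings, the counting program and its strand use are not given in the sources used here. Per the file headers, each deposited file holds a raw count per gene, made by the authors before scaling and given as whole numbers. Per the file headers, the deposited FPKM values are fragments scaled by the authors to gene length and library size, which the sources used here describe no further. The deposited TPM values equal the authors' FPKM rescaled to a fixed sum per library (largest difference 5.1e-11). Only the counts were used for tests. All 27 files held the same 33557 genes, and no line of a file was without a gene name. Coordinates are those of the files (TAIR10), written 1-based.

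The libraries made 21 groups, of which 6 had 2 libraries and 15 had 1. A 0 min library of the 17-to-27 experiment is numbered 1 in its title and 2 in its characteristics, and this number entered no test. Gene symbols came from a reference annotation by locus tag, which 32810 genes matched (97.77%). Starts were equal for 44.7% and ends for 44.25% of these, so no reference coordinate was used with the files' own.

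Genes were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 with robust settings, in R 4.3.3. The test is two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. A prior count of 2 entered the log2 fold changes per time in the plot of 3 gene lists. The tested fold changes did not use it, so those of genes with few control counts are less damped. HSP17.6II at 15 min was at 8.78 in the test and at 7.25 with this prior, and HSFA2 at 7.29 and 7.33. Effects at each time of the 17-to-27 experiment came from 1 group-means fit with 6 residual degrees of freedom. Effects over the 3 times had a term for each time, with 8 residual degrees of freedom for 27 °C and 2 for each of the other moves. Differences between moves used each experiment's own controls (10 degrees of freedom), and unshifted times had a term for each experiment (9 degrees of freedom). For lone libraries at a single time the spread came from the 6 duplicated groups. CPM (counts scaled to a common library size) used the TMM-scaled library sizes.

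Gene lists were small heat shock proteins; HSP70, HSP90, HSP100 and co-chaperones (larger chaperones in the text); heat shock factors; other heat-response genes; endoplasmic reticulum folding; and thermomorphogenesis and PIF targets. Further lists were auxin, brassinosteroids, the morning clock, the day and evening clock, cold-responsive genes, abscisic acid, touch with wound and jasmonate, and salicylic acid defence. The last were light harvesting and Rubisco, nucleolar ribosome biogenesis, S-phase histones and cell division, H2A.Z and SWR1, flowering regulators, root cell types and seed storage. These 21 lists with 311 members were written before the data were examined. Each was tested with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated. The version with an estimated correlation uses the residual degrees of freedom of the fit. With 2 of them, as for the 37 °C and 22-to-27 moves, it can hardly call any set. Fry, also run, asks whether a list changes at all without reference to other genes. Members expressed too little to pass the filter were not tested, so the number measured can be smaller than the list.

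Genes were named by a fixed rule. For each move over the 3 times these were the 8 highest and 8 lowest log2 fold changes among genes past the test, with a mean log2 CPM of at least 3 and the same sign at all 3 times. HSP70-4, HSFA2, HSP101, PIF4 and CCA1 were always given, and up to 4 members of a list were named, those with the largest changes past the test. Where all control counts were 0, a ratio was given as at least its value over 3 counts, and ratios of genes with 1 to 3 control counts over the group carry exact 95% intervals. Genes that share reads with near-identical copies, or overlap a neighbour or an antisense transcript, are uncertain, since the strand use of the counting is not known.

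Replicate numbers were checked for pairing by correlating each library's deviation from its group mean. Libraries with the same number at the same time had correlations from 0.42 to 0.56 (3 pairs), and those of different times from -0.07 to 0.39 (12 pairs), so the numbers pair libraries within a time. Duplicate libraries differed by far more than counting error, with a chi-square of 27.2 to 84.1 per degree of freedom.

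The tests were first run on simulated counts with 200 changed genes. Of 100 genes changed 4-fold, 74 were found at 15 min, 67 at 1 h, 80 at 4 h, 96 over the 3 times at 27 °C, 87 at 37 °C and 97 for the 22-to-27 move. Of 100 genes changed 2-fold, 12, 6, 11, 64, 42 and 63 were found. The change of effect found 35 and 2, the difference between moves 71 and 18 at 37 °C and 76 and 17 for 22-to-27, and unshifted times 93 and 70 at 15 min and 89 and 76 at 4 h. Borrowed spread at 15 min found 27 and 3 at 37 °C and 28 and 0 for the 22-to-27 move. False calls were 9 of 95 at 15 min, 5 of 78 at 1 h and 6 of 97 at 4 h. Over the 3 times they were 8 of 168 at 27 °C, 30 of 159 at 37 °C and 17 of 177 for 22-to-27. The change of effect had 1 of 38, and differences between moves 9 of 98 (37 °C) and 4 of 97 (22-to-27). Unshifted times had 8 of 171 at 15 min and 7 of 172 at 4 h. Borrowed spread had 1 of 31 at 37 °C and 6 of 34 for 22-to-27. The stop condition of this run was first that no changed gene come out in the wrong direction. It failed with 1 such gene at 15 min and was then relaxed to 1% of changed genes.

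Alternatives were RLE scaling, the Wald test of DESeq2 1.42.0, no filter, a mean CPM of at least 1, organelle genes left out and an absolute log2 fold change of at least 1. Replicate blocks, all 27 libraries in 1 fit, 17 °C libraries alone and single libraries or time pairs left out were further ones. Chosen after the data were seen were the block within each time, each time left out at 27 °C, and the 2 chloroplast-rich 1 h libraries left out.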

Results

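RNA from whole seedlings of Arabidopsis thaliana (Col-0) was sequenced after a sudden move to a warmer temperature, with seedlings left at their growth temperature collected beside them. The labels describe plants grown for 10 days at 17 °C in long days and shifted 1 h after dawn. The 27 libraries fell into 3 experiments. The 17-to-27 experiment had 13 libraries, with 2 at 17 °C and 2 at 27 °C at each of 15 min, 1 h and 4 h, and 1 taken at 0 min. The 17-to-37 and 22-to-27 experiments had 7 libraries each, 1 per temperature and time and 1 at 0 min, so their differences at a single time had no replicate. Growth at 22 °C is not described in the labels. Total counts per library ran from 6.40 to 30.74 M in the 17-to-27 experiment (median 14.79), from 15.30 to 22.48 M in the 17-to-37 experiment (median 18.44) and from 5.79 to 10.69 M in the 22-to-27 experiment (median 6.58). No label says that the libraries of a group came from separate cultures, so the p-values may measure technical spread only.

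The move from 17 to 27 °C raised genes of protein folding within the first 4 h. Small heat shock proteins, which keep unfolding proteins from clumping, rose furthest. Of their 19 genes 16 were higher (17 adjusted over the list alone), with a median log2 fold change of 3.89. The leading member was HSP17.6II (AT5G12020; chromosome 5, from 3882237 to 3882938, TAIR10), higher by 8.36 ± 0.82 on the log2 scale (SE, n = 6 libraries per temperature, edgeR adjusted p = 0.0032). HSP17.7 (8.32 ± 0.84), the mitochondrial HSP23.6 (8.19 ± 1.08), HSP17.4A (8.10 ± 0.85), HSP17.6C (6.88 ± 0.78), HSP17.8 (6.82 ± 0.96) and HSP17.6A (6.01 ± 0.90) followed. The value of HSP23.6 rests on 4 control counts, with 4 of 6 control libraries at 0, so its size is uncertain. HSP17.6II, HSP17.7, HSP17.4A and HSP17.6C had 15, 20, 21 and 17 control counts over 6 libraries, so their sizes and order are uncertain too. Larger chaperones of the HSP70, HSP90 and HSP100 families and their helpers rose in 14 of 31 cases (23 adjusted over the list alone). Among them were HSP90.1 (5.78 ± 0.62), the immunophilin ROF2 (5.31 ± 0.82), the co-chaperone HOP3 (5.06 ± 0.48) and HSP70-4 (AT3G12580; chromosome 3, from 3991261 to 3993792; 4.68 ± 0.44, adjusted p = 0.0023). HSP101, which pulls aggregates apart, rose by 4.06 ± 0.71 (AT1G74310; chromosome 1, from 27936508 to 27940190; adjusted p = 0.029).

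Heat shock factors, the transcription factors that switch such genes on, rose in 4 of 17 cases at 27 °C (adjusted over the list alone, 6 rose and 1 fell). They were HSFA2 (AT2G26150; chromosome 2, from 11135682 to 11137396; 5.80 ± 0.89, adjusted p = 0.019), HSFA7B (4.28 ± 0.88), HSFB2B (1.84 ± 0.24) and HSFB2A (1.34 ± 0.20). Other heat-response genes rose in 4 of 11 cases (5 adjusted over the list alone): the coactivator MBF1C (4.56 ± 0.49), the ascorbate peroxidase APX2 (2.47 ± 0.40) and the splicing factors SR45a (2.31 ± 0.29) and SR30 (1.60 ± 0.19). Endoplasmic reticulum folding genes moved less, with 5 of 18 higher (10 adjusted over the list alone). These included the co-chaperone ERDJ3A (2.54 ± 0.41), SDF2 (0.70 ± 0.14), ERDJ3B (0.67 ± 0.15) and the stress sensor BZIP28 (0.62 ± 0.11). As sets, limma camera gave adjusted p = 1.06e-30 for the small heat shock proteins and 4e-24 for the larger chaperones. It gave 0.00112 for the heat shock factors, 1.99e-07 for the other heat-response genes and 7.13e-09 for endoplasmic reticulum folding. The small heat shock proteins had adjusted p = 0.0252 with an estimated correlation. The other 4 sets gave adjusted p = 0.138, 0.103, 0.138 and 0.138 with an estimated correlation, in the order above.

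The falls at 27 °C were smaller. The 8 deepest among well-expressed genes had adjusted p from 0.013 to 0.049. They were AT5G20790 (-2.44 ± 0.42), the transporter ABCG27 (-1.48 ± 0.23), the aspartyl protease AT2G39710 (-1.30 ± 0.24) and ASE2 (-1.16 ± 0.19), which catalyses the first step of purine synthesis. The cytochrome P450 CYP702A5 (-1.07 ± 0.21), the cell-wall expansin EXPA11 (-0.95 ± 0.21), the glycosyltransferase AT2G36970 (-0.94 ± 0.20) and the protein kinase AT5G61570 (-0.94 ± 0.19) followed. Touch, wound and jasmonate early genes had a median of -0.46 with 0 of 23 past the test (camera adjusted p = 0.000417; adjusted p = 0.496 with an estimated correlation). Salicylic acid defence genes had a median of -0.27 with 0 of 14 past the test (adjusted p = 0.0163; adjusted p = 0.496 with an estimated correlation). Cold-responsive genes had a median of -0.44 with 0 of 16 (adjusted p = 0.0176; adjusted p = 0.524 with an estimated correlation). Genes of nucleolar ribosome biogenesis had a median of -0.26 with 0 of 10 past the test and 4 lower adjusted over the list alone (adjusted p = 7.48e-05, adjusted p = 0.325 with an estimated correlation).

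Light harvesting and Rubisco genes, which mark shoot tissue, had a median of 0.23 at 27 °C with 0 of 22 past the test (adjusted p = 0.0416, adjusted p = 0.851 with an estimated correlation). This set was no longer called with the replicate number as a block (adjusted p = 0.0688) or with a block within each time (0.0946). No member of the thermomorphogenesis list passed (0 of 15, 1 lower adjusted over the list alone, median 0.01, camera adjusted p = 0.841). PIF4, the bHLH factor that drives elongation in warmth (AT2G43010; chromosome 2, from 17886427 to 17889050), was at 0.49 ± 0.17 (adjusted p = 0.16). The clock gene CCA1 (AT2G46830; chromosome 2, from 19245672 to 19248914) was at -0.12 ± 0.09 (adjusted p = 0.54). Morning clock genes (0 of 10, 3 lower adjusted over the list alone, adjusted p = 0.42) and day and evening clock genes (0 of 10, adjusted p = 0.761) gave no call. Neither did auxin (0 of 18, adjusted p = 0.654), brassinosteroid (0 of 9, adjusted p = 0.37) or abscisic acid genes (0 of 12, adjusted p = 0.494). S-phase histones and cell division genes (0 of 15, 1 lower adjusted over the list alone, adjusted p = 0.654), flowering regulators (0 of 7, adjusted p = 0.117) and root cell type markers (0 of 12, adjusted p = 0.654) did not pass. The histone variant H2A.Z and its SWR1 loading complex had 0 of 9 past the test (adjusted p = 0.936), with a median of 0.02 and a mean of -0.11. No seed storage gene was expressed enough to be tested.

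In the test of 27C versus 17C over the 3 times, 315 of 20818 genes differed (193 higher, 122 lower, edgeR, adjusted p under 0.05). Replicate numbers paired the libraries within each time, and 487 genes passed with the replicate number as a block (266 higher, 221 lower). With a block within each time 551 passed (280 higher, 271 lower). Without the 1 h libraries 3 genes passed, against 189 without the 15 min and 93 without the 4 h libraries. Without the libraries numbered 1 the count was 33, and without those numbered 2 it was 20. The 1 h libraries numbered 1 held 5.43% (17 °C) and 6.45% (27 °C) chloroplast counts, against 0.252% and 0.214% in those numbered 2. Libraries numbered 1 also held more at 15 min, with 1.25% (17 °C) and 1.54% (27 °C) against 0.284% and 0.231%. At 4 h they held 0.816% and 0.433% against 0.209% and 0.374%. With both 1 h libraries numbered 1 left out 74 genes passed, 68 of them among the 315. This did not remove the smaller imbalance at the other times.

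Small heat shock proteins, larger chaperones, heat shock factors, other heat-response genes and endoplasmic reticulum folding genes were called at 27 °C in 16, 14, 4, 4 and 5 cases with all libraries. In the same order the counts were 1, 0, 0, 0 and 0 without the 1 h libraries, and 5, 0, 0, 1 and 0 without libraries numbered 1. They were 4, 4, 2, 2 and 1 without libraries numbered 2, and 11, 6, 2, 4 and 0 without the chloroplast-rich 1 h libraries. Without the 15 min libraries they were 11, 7, 1, 4 and 2, and without the 4 h libraries 11, 16, 3, 3 and 1. Median log2 fold changes in this order were 3.89, 0.93, 0.32, 1.19 and 0.52 with all libraries. The medians were 3.5, 0.82, 0.27, 0.81 and 0.31 without the 1 h libraries. Without libraries numbered 1 they were 5.15, 1.03, 0.07, 1.18 and 0.57.

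After 15 min at 27 °C heat shock factors and chaperones were among the genes that rose. HSFA2 rose by 7.29 ± 0.88 (SE, n = 2 per temperature), from 3.46 ± 1.93 to 548 ± 194 CPM (counts scaled to a common library size; SD). With HSFA7B (6.70 ± 0.87), HSFA7A (5.83 ± 0.85) and HSFB2B (2.76 ± 0.20) it made 4 of 19 heat shock factors past the test (5 higher and 2 lower adjusted over the list alone). In the same libraries 7 of 19 small heat shock proteins rose (14 adjusted over the list alone), led by HSP17.6II (8.78 ± 1.23), HSP17.6A (7.55 ± 0.82) and HSP17.8 (7.55 ± 0.78). With a prior count of 2 these were at 7.25, 7.38 and 7.37. Larger chaperones rose in 11 of 31 cases (26 adjusted over the list alone), led by HSP90.1 (6.52 ± 0.66), ROF2 (5.88 ± 0.67) and HSP101 (5.85 ± 0.59). Camera gave adjusted p = 1.01e-40 for small heat shock proteins, 1.18e-63 for larger chaperones, 0.00244 for heat shock factors and 1.98e-10 for other heat-response genes at 15 min. They gave adjusted p = 0.0309, 0.0309, 0.337 and 0.202 with an estimated correlation. The only fall was that of PROPEP3, the precursor of a danger-signal peptide (-2.86 ± 0.44), a gene named after its values were seen. For 27C versus 17C at 15 min, 47 of 21608 genes passed (46 higher, 1 lower), and 193 with a block within each time (138 higher, 55 lower). Without the 17 °C library numbered 1 there was 1, without the 17 °C library numbered 2 there were 2, and without the 27 °C library numbered 2 there were 8. With the replicate number as a block 3 more sets were called at 15 min, all lower: auxin genes (adjusted p = 0.0354, against 0.0583 unblocked), cold-responsive genes (0.0479, against 0.135) and flowering regulators (0.0473, against 0.0549). With a block within each time only the flowering regulators were called (adjusted p = 0.0421), and the auxin and cold-responsive genes were not (0.0545 each). Without a block the 3 sets gave adjusted p = 0.646, 0.692 and 0.413 with an estimated correlation. Shoot genes (adjusted p = 2.47e-05, adjusted p = 0.646 with an estimated correlation) and root markers (adjusted p = 0.0345, adjusted p = 0.478 with an estimated correlation) were called as higher at 15 min.

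After 1 h at 27 °C single genes of endoplasmic reticulum folding passed the test. SDF2 (1.19 ± 0.17), the calreticulin CRT1A (0.98 ± 0.17) and the calnexin CNX1 (0.92 ± 0.17) were higher (SE, n = 2 per temperature; 3 of 18, 11 adjusted over the list alone). As a set they were called at 1 h (camera adjusted p = 2.11e-09, adjusted p = 0.254 with an estimated correlation) and already at 15 min (adjusted p = 4.73e-06, adjusted p = 0.413 with an estimated correlation), when 0 of 18 passed singly. Of 19 small heat shock proteins 12 passed (16 adjusted over the list alone), led by HSP17.4A (10.21 ± 1.39) and HSP17.7 (9.65 ± 1.38). With a prior count of 2 these were at 9.10 and 8.56, so their sizes are uncertain. Larger chaperones passed in 10 of 31 cases (26 adjusted over the list alone), with ROF2 (7.03 ± 0.71), HSP90.1 (6.71 ± 0.67) and HOP3 (5.74 ± 0.56) in front. As sets, small heat shock proteins, larger chaperones, heat shock factors and other heat-response genes gave camera adjusted p = 8.9e-27, 1.62e-25, 0.00934 and 5.09e-07, and adjusted p = 0.151, 0.248, 0.349 and 0.26 with an estimated correlation. The lipoxygenase LOX4, of jasmonate synthesis, fell (-1.82 ± 0.34; 1 of 23 touch, wound and jasmonate genes, 5 adjusted over the list alone). The touch list (camera adjusted p = 5.01e-05) and salicylic acid defence (0.0165) were called as lower and the shoot list (0.00909) as higher, with adjusted p = 0.472, 0.472 and 0.943 with an estimated correlation. Nucleolar genes had a median of -0.46 with 0 of 10 past the test and 6 lower adjusted over the list alone (camera adjusted p = 3.1e-06, adjusted p = 0.254 with an estimated correlation). The comparison of 27C versus 17C at 1 h gave 182 genes (97 higher, 85 lower). With the replicate number as a block 449 passed (212 higher, 237 lower), and with a block within each time 1648 (701 higher, 947 lower). Without either 17 °C library edgeR called 0, without the 27 °C library numbered 1 it called 1 and without that numbered 2 it called 1317. With both libraries numbered 1 left out, 1 library per temperature remained. Small heat shock proteins then had a median log2 fold change of 4.1 (18 of 19 above 0) and larger chaperones of 0.93 (26 of 31). Heat shock factors (0.21, 11 of 19), other heat-response genes (0.89, 9 of 11) and folding genes (0.76, 16 of 18) followed. Without the 27 °C library numbered 1 the call was a small heat shock protein, and no other member of the heat or folding lists was called in that run. Without the 27 °C library numbered 2, 15 small heat shock proteins, 24 larger chaperones and 5 folding genes were. With a block within each time 16, 19 and 8 were called, and with the replicate number as a block 11, 13 and 6.

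After 4 h at 27 °C few genes passed the test, unless replicate numbers were blocked within each time. HSP70-4 stood at 139 ± 21.2 CPM against 13.3 ± 2.16 at 17 °C (SD, n = 2), compared with 1386 ± 604 against 44.3 ± 25.5 at 15 min. Small heat shock proteins still had a median of 3.14, with HSP18.1 (1.95 ± 0.23, SE) alone past the test (1 of 19, 16 adjusted over the list alone; camera adjusted p = 3.13e-21, adjusted p = 0.254 with an estimated correlation). The other genes past the test were named after their values were seen. They were the squalene epoxidase-like SQE6 (2.09 ± 0.22) and SQP1 (1.68 ± 0.21), CYP71B13 (2.01 ± 0.22), AT2G46250 (1.65 ± 0.19), PGRL1B (1.57 ± 0.16) and, lower, the early light-induced protein ELIP2 (-3.57 ± 0.36). In the test of 27C versus 17C at 4 h, 7 genes passed (6 higher, 1 lower), 17 with the replicate number as a block (7 higher, 10 lower) and 546 with a block within each time (222 higher, 324 lower). Leaving out any 1 of the 4 libraries left 0 or 1. Larger chaperones (camera adjusted p = 0.00156), endoplasmic reticulum folding (0.000395), other heat-response genes (0.0171) and heat shock factors (0.0338) were called as higher. In this order they gave adjusted p = 0.479, 0.414, 0.479 and 0.414 with an estimated correlation. Cold-responsive genes (median -0.91, camera adjusted p = 7.05e-05), salicylic acid defence (0.000118), the touch list (0.000177), nucleolar genes (0.000209) and root markers (median -0.40, 0.00501) were called as lower at 4 h. With an estimated correlation the touch list gave adjusted p = 0.414 and the other 4 adjusted p = 0.41. Auxin genes were called as higher (adjusted p = 0.0323, adjusted p = 0.479 with an estimated correlation).

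**Figure D1:**
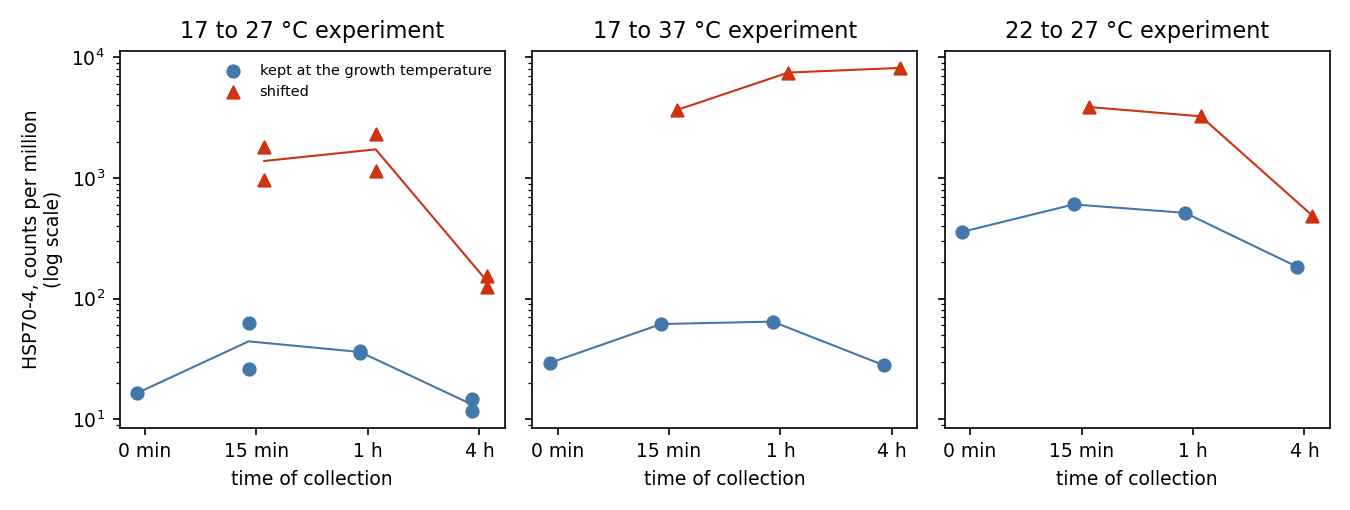
HSP70-4 transcript level (CPM, log axis) against time of collection in the 3 experiments; each point is a library and lines join group means of shifted (red) and kept (blue) seedlings. At 27 °C from 17 °C the mean was 1386 at 15 min and 139 at 4 h, while at 37 °C the level was highest at 4 h.

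The change of the 27C effect from 15 min to 4 h was tested as a difference of the 2 effects. Larger chaperones had a median difference of -1.30 and 0 of 31 past the test (19 lower adjusted over the list alone; camera adjusted p = 5.54e-22, adjusted p = 0.352 with an estimated correlation). The difference of the small heat shock proteins, with a median of -1.20, gave camera adjusted p = 0.0626. Salicylic acid defence genes had a median difference of -1.12 (adjusted p = 6.2e-05, adjusted p = 0.352 with an estimated correlation). Touch (0.000277), root (0.000227), shoot (8.26e-05), nucleolar (0.00211), cold-responsive (0.00958) and other heat-response genes (0.019) were also called as lower, and none was with an estimated correlation (adjusted p from 0.352 to 0.542). Auxin genes moved the other way (median 0.41, adjusted p = 0.00269, adjusted p = 0.542 with an estimated correlation). S-phase histones and cell division genes were called (median -0.33, adjusted p = 0.038, adjusted p = 0.542 with an estimated correlation) but not with the replicate number as a block (adjusted p = 0.079), and again with a block within each time (adjusted p = 0.0159). No single gene passed in edgeR (0 of 21608, 1641 at an unadjusted p under 0.05), against 129 in DESeq2 (17 higher, 112 lower). With the replicate number as a block 1 passed, and with a block within each time 71 (11 higher, 60 lower).

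The move from 17 to 37 °C raised heat shock genes further. Small heat shock proteins were higher in 17 of 19 cases (17 adjusted over the list alone), with a median log2 fold change of 8.50. The chloroplast protein HSP21 led (AT4G27670; chromosome 4, from 13818870 to 13819971; 10.22 ± 0.46, SE, n = 3 libraries per temperature, edgeR adjusted p = 0.00089), with HSP23.6 (9.76 ± 0.38), the endoplasmic reticulum protein HSP22 (9.40 ± 0.62) and HSP17.6II (9.29 ± 0.31). Larger chaperones rose in 28 of 31 cases (31 adjusted over the list alone). These included BAG6 (9.08 ± 0.25), HSP70-5 (8.66 ± 0.41), HSP70-8 (8.54 ± 0.16), HSP90.1 (8.54 ± 0.45), HSP101 (8.02 ± 0.48) and HSP70-4 (6.97 ± 0.55). Of 17 heat shock factors 5 rose (1 fell besides, adjusted over the list alone), among them HSFA7B (9.37 ± 0.21) and HSFA2 (8.98 ± 0.46). Other heat-response genes rose in 9 of 11 cases (9 adjusted over the list alone), among them APX2 (8.77 ± 0.31), MBF1C (6.98 ± 0.48), the dehydration-response factor DREB2A (5.98 ± 0.54) and the galactinol synthase GOLS1 (5.64 ± 0.11). APX2 had 11 control counts in all, so the size of its rise is uncertain. Endoplasmic reticulum folding genes split, with 6 of 18 higher and 2 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.144). ERDJ3A (6.46 ± 0.26) and BIP1 (2.01 ± 0.18) rose, and CRT1A (-1.09 ± 0.16) and the disulfide isomerase PDIL2-1 (-1.06 ± 0.15) fell.

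Root cell type markers were lower at 37 °C in 7 of 12 cases (8 adjusted over the list alone, median -1.35). They included the nitrate transporter NRT2.1 (-3.94 ± 0.80), the root hair expansins EXPA18 (-2.99 ± 0.26) and EXPA7 (-2.50 ± 0.46) and the peroxidase PER64 (-2.08 ± 0.23), while CASP1 (-0.22 ± 0.12) and SCR (0.11 ± 0.21) did not pass. Auxin genes fell in 5 of 16 cases and rose in 1 (the same adjusted over the list alone; camera adjusted p = 0.161). The falls included SAUR20 (-5.07 ± 0.55), SAUR21 (-2.24 ± 0.48), SAUR24 (-2.04 ± 0.40) and the repressor IAA3 (-1.42 ± 0.13), and the rise was that of the auxin synthesis gene YUC9 (1.08 ± 0.24). SAUR20 had 3 counts in all at 37 °C, against 138 at 17 °C, so the size of its fall is uncertain. The deepest falls among well-expressed genes were AT1G63130, a tetratricopeptide repeat protein (-5.27 ± 0.60), AT5G54370 (-4.41 ± 0.82) and the beta-glucosidases BGLU33 (-4.24 ± 0.39), BGLU34 (-4.16 ± 0.75) and BGLU21 (-3.65 ± 0.57). The SAUR-like AT2G21210 (-3.85 ± 0.54), the lipase-like GLL22 (-3.80 ± 0.22) and the peroxidase Prx37 (-3.57 ± 0.58) completed the 8. S-phase histones and cell division genes fell in 4 of 15 cases (5 adjusted over the list alone; HTA13 -1.21 ± 0.22, HTR9 -0.76 ± 0.12; camera adjusted p = 0.0798).

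Morning clock genes were higher in 5 of 10 cases at 37 °C (5 adjusted over the list alone). RVE1 rose by 1.31 ± 0.28, RVE4 by 0.70 ± 0.12 and RVE6 to 2.46 times its control level, and CCA1 was at 0.79 ± 0.30 (adjusted p = 0.12). In the shoot list the 4 of 22 genes that rose (4 adjusted over the list alone) belonged to Rubisco, the carbon-fixing enzyme, and its activase. They were RBCS1B (0.93 ± 0.10), RBCS2B (0.57 ± 0.09), RCA (0.54 ± 0.09) and RBCS3B (0.40 ± 0.09). Abscisic acid genes rose in 3 of 12 cases, the synthesis gene NCED3 (2.80 ± 0.43), HAI1 (2.36 ± 0.25) and ABF3 (1.03 ± 0.19), and the catabolic CYP707A3 fell (-0.86 ± 0.21; the same counts adjusted over the list alone; camera adjusted p = 0.285). Cold-responsive genes rose in 3 of 15 cases (4 adjusted over the list alone; COR27 1.95 ± 0.45, COR47 1.43 ± 0.18; camera adjusted p = 0.174). Salicylic acid defence genes fell in 3 of 12 (PR5 -1.35 ± 0.20, SAG101 -1.09 ± 0.17, PAD4 -0.88 ± 0.18; 3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.267).

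Touch, wound and jasmonate genes went both ways at 37 °C (2 of 22 higher, 3 lower; 3 and 4 adjusted over the list alone; camera adjusted p = 0.87). ZAT12 (3.03 ± 0.37) and TCH3 (0.84 ± 0.12) rose, and ERF5 (-2.06 ± 0.34), ERF2 (-1.40 ± 0.29) and OPR3 (-0.59 ± 0.13) fell. HY5, a factor that restrains elongation in light, was the only thermomorphogenesis gene past the test (1.26 ± 0.29; 1 of 15, 0 adjusted over the list alone; camera adjusted p = 0.611), and PIF4 was at -0.77 ± 0.46 (adjusted p = 0.26). In the H2A.Z list HTA4 fell (-3.99 ± 0.67) and HTA9 (0.54 ± 0.11) and ARP6 (0.49 ± 0.12) rose. That list had 3 of 9 past the test (3 higher and 2 lower adjusted over the list alone), a median of 0.03, a mean of -0.40 and camera adjusted p = 0.87 upward. HTA4 had 3 counts in all at 37 °C, against 65 at 17 °C, so the size of its fall is uncertain. Of the brassinosteroid genes BZR1 rose (0.64 ± 0.15), and DWF4 (-0.89 ± 0.22) and BAS1 (to 0.251 of its control level) fell (3 of 9; 1 higher and 3 lower adjusted over the list alone; adjusted p = 0.611). ELF3 rose in the day and evening clock list (0.46 ± 0.11; 1 of 10, 0 adjusted over the list alone, adjusted p = 0.17) and the flowering repressor FLC in its list (0.96 ± 0.18; 1 of 7, 1 adjusted over the list alone, adjusted p = 0.611). Nucleolar genes did not pass (0 of 10, adjusted p = 0.701), nor did CRA1 (-1.01 ± 0.69), the only seed storage gene tested (adjusted p = 0.653 as a list).

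The sets called at 37 °C were the small heat shock proteins (camera adjusted p = 2.3e-18), the larger chaperones (1.39e-24), the heat shock factors (0.00888) and the other heat-response genes (3.81e-09). Root markers (0.00118), the morning clock (0.00246) and the shoot list (0.00564) were also called. The 4 heat sets gave adjusted p = 0.593 with an estimated correlation, and the last 3 gave adjusted p = 0.634, 0.701 and 0.709 with an estimated correlation. On 2 residual degrees of freedom that version can hardly call any set, so these values decide nothing. In the test of 37C versus 17C over the 3 times, 4476 of 21077 genes passed (2089 higher, 2387 lower), on 2 residual degrees of freedom. Without the 1 h pair 445 passed, and 30 of 159 calls were false on simulated counts of this design. Without that pair 17 of 19 small heat shock proteins were called, as with it, but 17 larger chaperones in place of 28, 7 other heat-response genes in place of 9 and 2 endoplasmic reticulum folding genes in place of 6. At single times, with the spread borrowed from the duplicated groups, 546 genes passed at 15 min (328 higher, 218 lower), 1075 at 1 h (485 higher, 590 lower) and 3395 at 4 h (1370 higher, 2025 lower). These counts assume that the lone libraries vary like the duplicated ones.

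Several of the highest values at 37 °C belonged to genes nearly silent at 17 °C. PUM21 (AT5G09610; chromosome 5, from 2981156 to 2982709), which encodes a pumilio-type RNA-binding protein, rose by 11.60 ± 0.22 and the DnaJ-domain chaperone AT1G71000 by 10.86 ± 0.30 (SE, n = 3). With 4 and 9 control counts in all, the sizes of these 2 changes are uncertain. The mitochondrial gene ATMG00630 had 0 counts in the 3 control libraries and was at least 408-fold higher, against a floor of 3 counts over the group. Genes with 1 control count had ratios of 4740 for AT1G21940 (95% interval 850 to 187000), 3590 for AT1G30060 (644 to 142000) and 2770 for the F-box gene AT1G53550 (496 to 109000). Such intervals and floors cover counting error only. By locus number AT1G53550 comes next after HSP17.6C (AT1G53540). With a prior count of 2 they rose by 7.74, 9.17 and 7.79 and by 7.76, 8.59 and 9.67 at 15 min, 1 h and 4 h. Genes next to strongly induced ones were often higher at 37 °C. How much a neighbour added to the values in this paragraph was not tested. All 98 mitochondrial genes tested were higher at 37 °C. Of these, 21 without control counts and 23 more with 1 to 3 passed the filter only through the 37 °C libraries. The filter thus partly fixed the count. The share of counts on all mitochondrial genes was 0.152%, 0.265% and 0.448% at 15 min, 1 h and 4 h, against 0.0292% to 0.0412% in the 17 °C libraries of that experiment.

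**Figure D2:**
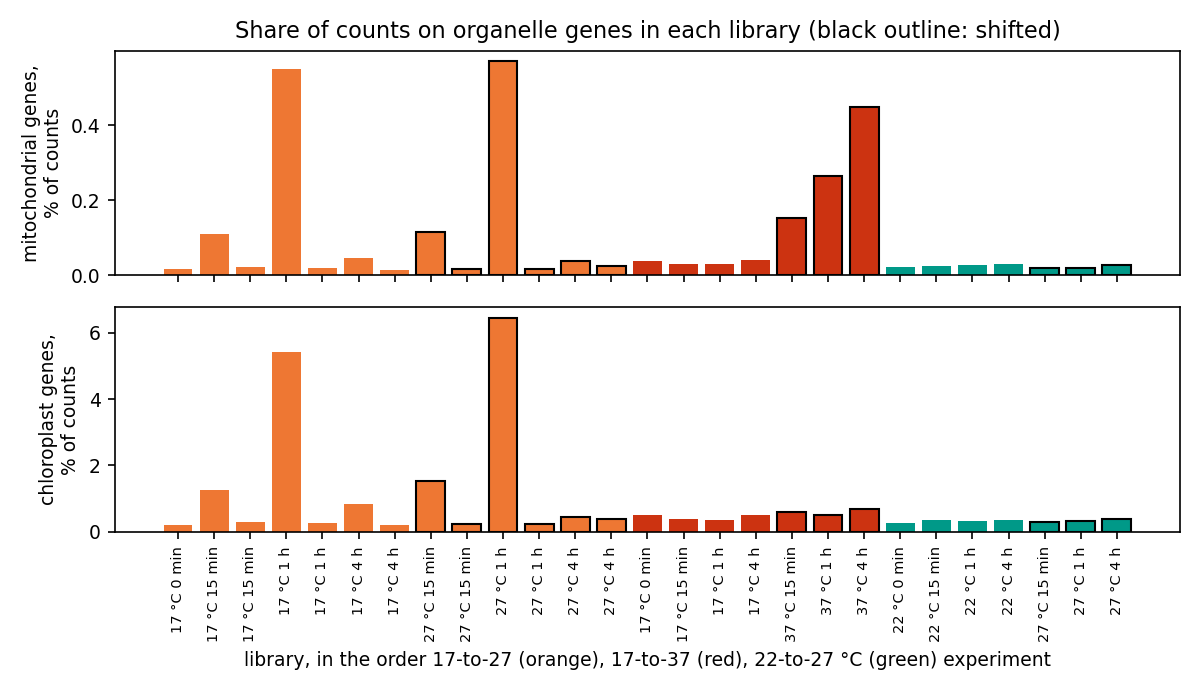
Share of counts on mitochondrial (upper) and chloroplast genes (lower) in percent; each bar is a library, coloured by experiment and outlined in black where shifted. At 37 °C the mitochondrial share was highest at 4 h, while in the 17-to-27 experiment both shares were high in the same 1 h libraries.

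Heat-response genes and mitochondrial genes were among those whose effect differed between 37 and 27 °C. Larger chaperones rose further at 37 °C in 25 of 31 cases (29 adjusted over the list alone), HSP70-5 by 7.20 ± 0.68 (SE, n = 3 and 6 libraries per temperature), BAG6 by 63.8-fold and HSP70-8 by 5.15 ± 0.57. Of the small heat shock proteins 9 of 19 did (10 adjusted over the list alone), including HSP21 (6.82 ± 1.21), HSP26.5 (6.42 ± 0.69) and HSP18.1 (6.39 ± 0.42). Other heat-response genes did in 7 of 11 cases (8 adjusted over the list alone, median 2.44; camera adjusted p = 3.53e-06, adjusted p = 0.213 with an estimated correlation). Of 98 mitochondrial genes 56 had a higher effect at 37 °C, and in the 17-to-37 experiment 21 of 98 had no counts and 23 more had 1 to 3 counts at 17 °C. Root markers were lower by this measure in 5 of 12 cases (6 adjusted over the list alone; EXPA18 -3.17 ± 0.44, EXPA7 -3.07 ± 0.46). Auxin genes were lower in 4 of 18 (5 lower and 1 higher adjusted over the list alone), with SAUR19 at -6.14 ± 1.62 and SAUR20 at -5.25 ± 0.80. SAUR20 had 3 counts in all at 37 °C, so the size of its difference is uncertain. The size for SAUR19 is uncertain too. With a prior count of 2 it was at -1.15, -1.72 and -1.73 at 15 min, 1 h and 4 h at 37 °C. At 27 °C it was at -0.57, 1.54 and 1.59. Morning clock genes were higher in 4 of 10 (8 adjusted over the list alone; RVE6 1.71 ± 0.29, CCA1 0.91 ± 0.25). For larger chaperones, small heat shock proteins, root markers, auxin genes and the morning clock, camera gave adjusted p = 2.94e-18, 1.49e-09, 0.00176, 0.0847 and 0.000184. They gave adjusted p = 0.213, 0.213, 0.291, 0.689 and 0.213 with an estimated correlation. Cold-responsive genes, on balance higher at 37 °C, passed only with the replicate number as a block (adjusted p = 0.0395) or a block within each time (0.0457, against 0.0506 unblocked, and adjusted p = 0.689 with an estimated correlation). In the test of the 37C effect minus 17-to-27C effect, 3447 of 21778 genes passed (1394 higher, 2053 lower), and 2098 or 1153 without the 17-to-27 libraries numbered 1 or 2.

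The move from 22 to 27 °C raised small heat shock proteins among others. HSP17.6C rose by 6.71 ± 0.61 (SE, n = 3 libraries per temperature, edgeR adjusted p = 0.034), HSP17.4A by 6.43 ± 0.59 and HSP15.7 by 3.36 ± 0.43. TIN1, a gene induced when folding in the endoplasmic reticulum is blocked, rose by 3.02 ± 0.28 and HSP70-4 by 2.25 ± 0.28. Small heat shock proteins passed in 4 of 18 cases (14 adjusted over the list alone, median 3.31) and larger chaperones in 1 of 31 (18 adjusted over the list alone). HSFA2 (3.75 ± 0.79, adjusted p = 0.16) and HSP101 (3.02 ± 0.82, adjusted p = 0.21) did not pass. The other highest values were AT5G25450 (3.54 ± 0.39), AT1G59265 (2.62 ± 0.26), the leucine-rich repeat gene AT2G15880 (2.47 ± 0.21) and the asparagine synthetase ASN1 (2.14 ± 0.19). The deepest falls were the peroxidase AT2G18150 (-2.38 ± 0.33), the root ferric reductase FRO2 (-2.25 ± 0.19), AT2G39710 (-1.41 ± 0.17), AT5G41900 (-1.24 ± 0.17) and the jasmonate-responsive VSP2 (-1.16 ± 0.14). AT3G28220 (-1.15 ± 0.13), AIR12 (-1.01 ± 0.13) and OPCL1, of jasmonate synthesis, at 0.5 of its control level, followed. PIF4 was at 0.47 ± 0.20 (adjusted p = 0.30) and CCA1 at 0.10 ± 0.15 (adjusted p = 0.77).

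The comparison of 22C to 27C over the 3 times gave 59 of 19063 genes (49 higher, 10 lower). The count was 251 without the 15 min pair, 0 without the 1 h pair and 405 without the 4 h pair. Small heat shock proteins were then called in 2, 0 and 12 cases and larger chaperones in 1, 0 and 19. Median log2 fold changes of the small heat shock proteins were 2.95, 3.34 and 4.3 in these runs (3.31 with all pairs). Those of the larger chaperones were 0.43, 0.63 and 1.1 (0.78 with all pairs). As sets, camera called the small heat shock proteins (adjusted p = 5.76e-15), the larger chaperones (6.86e-16), the other heat-response genes (0.00272; SR30 1.29 ± 0.19), endoplasmic reticulum folding (0.00046) and the heat shock factors (0.0216; HSFB2A 1.28 ± 0.15). Cold-responsive genes (median -0.67, 0.00046) and S-phase and cell division genes (median -0.36, 0.00046) were called as lower. The S-phase set gave adjusted p = 0.58 and each other set adjusted p = 0.556 with an estimated correlation. The morning clock (0.0284), the day and evening clock (0.0215), abscisic acid (0.0284, lower), root (0.045, lower) and nucleolar genes (0.045, lower) were called too, and none was with an estimated correlation (adjusted p = 0.556, and 0.687 for the nucleolar list). The version with an estimated correlation had 2 residual degrees of freedom here and can hardly call any set. With the spread borrowed, edgeR called 0 genes at 15 min and 0 at 1 h (720 and 1099 at an unadjusted p under 0.05), against 57 and 37 in DESeq2. At 4 h it called 4 (110 in DESeq2), named after their values were seen: AT2G46250 (2.34 ± 0.28), AT2G17630 (-2.12 ± 0.25), the flavonol synthase FLS1 (-3.49 ± 0.35) and the cell-wall enzyme XTH20 (-3.53 ± 0.40).

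The 22-to-27 and 17-to-27 effects were compared directly. Morning clock genes had higher values from 22 °C in 10 of 10 cases (median difference 0.35, 0 past the test singly; camera adjusted p = 0.000474, adjusted p = 0.0448 with an estimated correlation). S-phase and cell division genes had none of 15 above 0 (median -0.31; adjusted p = 0.000166, adjusted p = 0.755 with an estimated correlation). The day and evening clock and the touch list were called as higher (both adjusted p = 0.0299, adjusted p = 0.755 with an estimated correlation). The small heat shock proteins had a median difference of -0.87 (adjusted p = 0.0138, adjusted p = 0.755 with an estimated correlation). No gene differed in edgeR (0 of 21007, 858 at an unadjusted p under 0.05) or in DESeq2 (0).

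The 3 moves overlapped in the genes they raised, and no control library was shared between them. Of 20473 genes tested at both 27 and 37 °C, 134 rose in both against 16.2 for independent lists (hypergeometric exact one-sided p = 1.27e-98) and 30 fell in both against 13.8 (exact one-sided p = 2.91e-05). Of the 312 genes called at 27 °C 264 (84.6%) had the same sign at 37 °C. For 17-to-27 and 22-to-27, 20 rose in both against 0.5 (exact one-sided p = 6.89e-28), 1 fell in both (AT2G39710), and 292 of 299 called genes (97.7%) had the same sign. For 22-to-27 and 37 °C, 24 rose in both against 4.2 (exact one-sided p = 1.63e-13) and 7 fell in both against 1.2 (exact one-sided p = 3.01e-05). Pearson's r of the log2 fold changes over genes was 0.401, 0.605 and 0.409 for these pairs of moves. Genes are not independent, so the overlap p-values are too small.

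**Figure D3:**
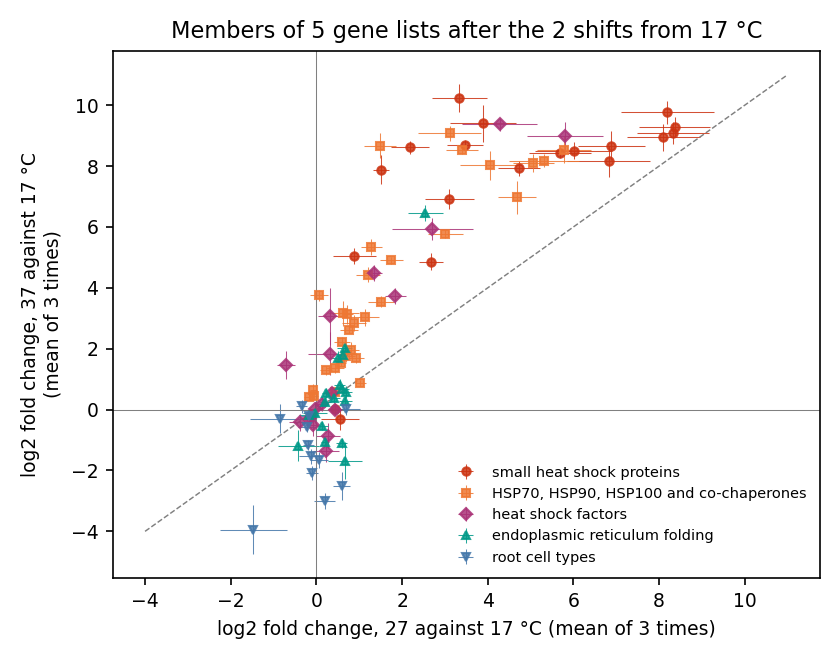
Log2 fold change at 37 °C against that at 27 °C, each against 17 °C and averaged over 3 times; each point is a gene of 5 lists with its SE, and the dashed line marks equal effects. Most small heat shock proteins and larger chaperones lie above the line, and most root cell type genes lie below it.

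**Figure D4:**
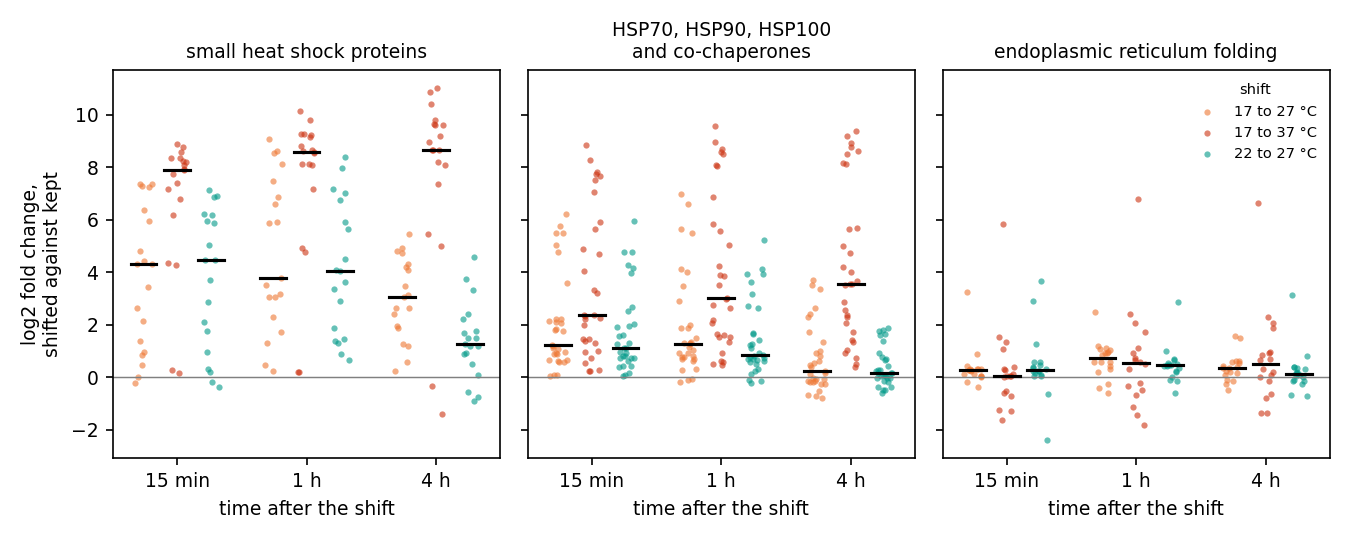
Log2 fold change (prior count of 2, unlike the tested values) of shifted against kept seedlings at 15 min, 1 h and 4 h for 3 gene lists. Each point is a gene, coloured by shift, and black bars are medians. The median of the small heat shock proteins went from 4.34 at 15 min to 3.06 at 4 h for 17 to 27 °C, from 4.46 to 1.28 for 22 to 27 °C and from 7.90 to 8.66 for 17 to 37 °C.

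Seedlings that stayed at their growth temperature also changed within 15 min. Touch, wound and jasmonate early genes rose in 13 of 23 cases (18 adjusted over the list alone), with 23 of 23 positive and a median of 2.60. WRKY40 (5.64 ± 0.82), the jasmonate repressors JAZ7 (5.58 ± 0.76) and JAZ8 (5.39 ± 0.96) and the zinc-finger factor ZAT10 (4.37 ± 0.35) led (SE, n = 3 libraries at 0 min and 4 at 15 min, adjusted p from 4.5e-05 to 0.0095). The cold-response regulators CBF1 (7.07 ± 0.76), CBF2 (5.35 ± 0.43) and CBF3 (1.90 ± 0.35) rose with them (3 of 16 cold-responsive genes, 4 adjusted over the list alone). So did the defence regulators WRKY70 (2.60 ± 0.29), SARD1 (2.57 ± 0.36), CBP60G (2.49 ± 0.26) and PAD4 (0.65 ± 0.14; 4 of 14, 7 adjusted over the list alone). Camera gave adjusted p = 3.51e-41 for the touch list, 1.17e-10 for salicylic acid defence and 7.21e-10 for cold-responsive genes. They gave adjusted p = 0.0106, 0.00132 and 0.123 with an estimated correlation. Abscisic acid genes (2.73e-05), heat shock factors (0.0139), larger chaperones (0.0092) and the thermomorphogenesis list (0.0477) were called too, and gave adjusted p = 0.375, 0.285, 0.462 and 0.199 with an estimated correlation. In the test of unshifted 15 min versus 0 min, 367 of 21035 genes passed (359 higher, 8 lower). Without the 17-to-27 library of 0 min 144 passed, without the 22 °C library of 0 min 216 and in the 17 °C libraries alone 154.

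Clock and light harvesting genes of unshifted seedlings differed between 0 min and 4 h. The dawn genes LHY (-3.33 ± 0.13), RVE8 (-1.97 ± 0.12) and CCA1 (-1.84 ± 0.10) fell and the later PRR7 rose (2.55 ± 0.14; SE, n = 3 libraries at 0 min and 4 at 4 h). Of 10 morning clock genes 7 were lower and 1 higher (the same adjusted over the list alone; camera adjusted p = 0.00011, adjusted p = 0.233 with an estimated correlation). Light harvesting and Rubisco genes rose in 15 of 22 cases (16 adjusted over the list alone), led by LHCB1.2 (0.88 ± 0.17) and LHCA4 (0.86 ± 0.19; camera adjusted p = 6.07e-06, adjusted p = 0.869 with an estimated correlation). Salicylic acid defence (adjusted p = 0.00039) and cold-responsive genes (0.0332) were called as higher and larger chaperones (0.00626) as lower, with adjusted p = 0.0573, 0.869 and 0.869 with an estimated correlation. PIF4 rose by 2.57 ± 0.31 and HY5 fell (-1.87 ± 0.16). Touch list genes were still higher in 11 of 23 cases (12 adjusted over the list alone), with CML38 at 3.76 ± 0.59 (camera adjusted p = 8.36e-05, adjusted p = 0.869 with an estimated correlation). For unshifted 4 h versus 0 min, 4829 genes passed (2499 higher, 2330 lower). Without the 17-to-27 library of 0 min 2906 passed, without the 22 °C library of 0 min 3124 and in the 17 °C libraries alone 2666. No library separates the time of day from handling at collection.

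HSP70-4, a heat-inducible chaperone, lay higher in unshifted seedlings of the 22-to-27 experiment than in those kept at 17 °C. The 4 libraries at 22 °C held 185 to 605 CPM (median 437) and the 11 at 17 °C held 11.8 to 64.6 (median 29.3; two-sided exact permutation p = 0.00073, the smallest that 1365 splits can give). Growth temperature went with the experiment in these libraries, which also cover several times of day. The permutation took single libraries as exchangeable, so its p-value cannot separate growth temperature from the experiment.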

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

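The tests in this part on organelle carry-over, kits, neighbouring genes and time of day were chosen only after the result was seen. A difference between groups was the reason for each item. The 37 °C effect differed from the 27 °C effect in 3447 genes. Of the genes called in both moves, 3 were higher at 27 °C and lower at 37 °C, against 22.4 for independent lists. CRT1A, a calreticulin of the endoplasmic reticulum, went from 0.59 ± 0.13 to -1.09 ± 0.16 (log2, SE; difference -1.67, adjusted p = 0.00038). AT1G72645 went from 0.67 ± 0.15 to -1.09 ± 0.22 (difference -1.75, adjusted p = 8e-04), and the amino acid permease AAP7 from 1.02 ± 0.22 to -1.73 ± 0.37 (difference -2.74, adjusted p = 0.00087). The reverse was seen in 1 gene against 10 for independent lists, AT1G70630, which went from -0.70 ± 0.14 to 1.23 ± 0.26 (difference 1.95, adjusted p = 0.00034). All 4 genes were named after their values were seen, and n was 6 libraries per temperature at 27 °C and 3 at 37 °C.

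Mitochondrial transcripts were higher at 37 °C in 98 of 98 genes tested, with a median log2 fold change of 5.86, or 5.36 with the 21 genes without control counts at their bound. These 21 and 23 more with 1 to 3 control counts passed the filter only through the 37 °C libraries. The filter thus partly fixed the count of 98. At 27 °C the median was 0.08 over the 31 genes that passed the filter there, a smaller set. More organelle RNA without poly(A) tails carried into the 37 °C libraries would raise chloroplast genes alike, as in the 1 h library numbered 1 at 17 °C, which exceeded its duplicate by 4.49 over 54 mitochondrial and 4.52 over 119 chloroplast genes. Chloroplast genes at 37 °C had a median of 0.69 (with their upper quartile below the mitochondrial lower quartile of 5.08), which speaks against carry-over of both organelles. Reads of nuclear copies cannot be told apart from mitochondrial reads. All 99 tested nuclear genes with at least 90% of their 31-base stretches in the mitochondrial genome were higher too (median 5.92). At 27 °C 22 such genes passed the filter, so the filter may have partly fixed the count of 99 as well. Another kit or centre for the 37 °C libraries cannot be told apart either, as the own labels of 0 libraries name one.

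Genes next to strongly induced genes were often higher at 37 °C. Of the downstream neighbours of 340 nuclear genes raised by a log2 fold change above 3, 154 of 291 were called higher (52.9%), against 8.9% next to unchanged genes. Reads spilling over from an abutting gene were tested with neighbours more than 1000 bases away (34.8% against 6.8%). Copies of the same gene were tested with neighbours that share no 31-base stretch (51.2% against 9.5%). Neither accounts for all of the rise. The lower share at a distance (34.8%, against 52.9% of all downstream neighbours) leaves a part for spill-over open. Related genes that share no 31-base stretch were not set apart. Transcription running on past the end of induced genes cannot be told apart from other causes: only the downstream neighbour was higher for 67 genes and only the upstream one for 44 (60.4% downstream), against 182 and 146 next to unchanged genes (55.5%, two-sided exact p = 0.38), and upstream neighbours of induced genes were called higher in 40.4%, against 6.9% next to unchanged genes. Genes with mitochondrial sequence were left out, and unchanged genes taken as the reference for the 2 sides, only after first results had been seen (62.2% of downstream neighbours with those genes in), and neighbouring genes are not independent.

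Touch, wound and jasmonate genes were higher at 15 min in unshifted seedlings of all 3 experiments, with 23 of 23 positive in each. Handling in 1 of the 3 experiments is argued against by the lowest of their medians, 1.88. Deeper 15 min libraries are argued against by the experiment whose 15 min library was the shallower (9.16 against 10.69 M counts), with a median of 3.17. Time of day cannot be told apart from handling at collection, since no library was taken untouched after 15 min, and at 4 h the median was 1.147.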

How the results depend on the processing

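The tests with a block within each time, with a time left out at 27 °C and without the chloroplast-rich libraries were chosen only after the result was seen. Of the values of named genes under other settings, 2774 kept direction and side of the threshold, 645 were no longer past it, 2 passed newly in DESeq2 (CCA1 at 37 °C, 0.80, and HSFA2 in the 22-to-27 move, 3.43) and 1, not past the test either way, changed sign (CCA1 in the 22-to-27 move, from 0.10 to -0.01 without the 1 h pair). Of the list values 38 kept their call and 140 were weaker. Blocks changed no other list call than those given beside the results. The cause was not tested for any count below, except that a fold threshold passes fewer genes by construction. RLE scaling, organelle genes left out, a mean CPM of at least 1 and 1 fit of all libraries kept every count within 1.5 times. Depth was lowest in the 22-to-27 experiment, with a median of 6.58 M counts, and its effect on the counts was not tested.

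For 27C versus 17C at 15 min (47) DESeq2 gave 157 (136 higher, 21 lower) and the block within each time 193. Single libraries left out gave 1 to 50. For 27C versus 17C at 1 h (182) DESeq2 gave 842 (407 higher, 435 lower), the replicate block 449 and the block within each time 1648. Single libraries left out gave 0 to 1317, and both libraries numbered 1 left out gave 0. For 27C versus 17C at 4 h (7) DESeq2 gave 376 (133 higher, 243 lower), no filter 20, the replicate block 17 and the block within each time 546, and single libraries left out gave 0 to 1. For the change of the 27C effect from 15 min to 4 h (0) DESeq2 gave 129, no filter 1, the replicate block 1 and the block within each time 71.

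For 27C versus 17C over the 3 times (315) DESeq2 gave 1180 (608 higher, 572 lower), an absolute log2 fold change of at least 1 124, the replicate block 487 and the block within each time 551. Leaving out libraries numbered 1 or 2 gave 33 or 20, times left out gave 3 to 189, and the chloroplast-rich libraries left out gave 74. For 37C versus 17C over the 3 times (4476) the fold threshold gave 2617 (1042 higher, 1575 lower) and pairs left out gave 445 to 3735. For 22C to 27C over the 3 times (59) DESeq2 gave 354 (213 higher, 141 lower), no filter 225 (138 higher, 87 lower) and pairs left out gave 0 to 405, with 251 between.

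For the 37C effect minus 17-to-27C effect (3447) the fold threshold gave 2227 (778 higher, 1449 lower), and libraries numbered 1 or 2 left out gave 2098 or 1153. For the 22-to-27C effect minus 17-to-27C effect every setting gave 0. For unshifted 15 min versus 0 min (367) DESeq2 gave 613 (586 higher, 27 lower), 17 °C libraries alone 154, and single libraries left out 144 to 336. For unshifted 4 h versus 0 min (4829) the fold threshold gave 1810 (1147 higher, 663 lower), 17 °C libraries alone 2666, and single libraries left out 2906 to 5243. For 22C to 27C at 15 min, spread borrowed (0), DESeq2 gave 57 and no filter 1. For 22C to 27C at 1 h, spread borrowed (0), DESeq2 gave 37, and for 22C to 27C at 4 h, spread borrowed (4), it gave 110. Counts at 37 °C with borrowed spread stayed within 1.5 times.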

Other observations

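The tests of other splits in this part were chosen only after the result was seen. Single genes of flowering and of the clock differed in unshifted seedlings between 0 min and 4 h, while the flowering list (3 of 7 higher, 1 lower, the same adjusted over the list alone; camera adjusted p = 0.619) and the day and evening clock list (3 of 10 higher, 1 lower; 0.62) were not called. CO, the day-length sensor of flowering, fell (-2.66 ± 0.29, log2, SE, n = 3 libraries at 0 min and 4 at 4 h, adjusted p = 4.1e-05), while its partner FKF1 (3.03 ± 0.61) and the clock repressor PRR5 (2.69 ± 0.40) rose. FT, the mobile flowering signal, rose by 1.83 ± 0.50, SOC1 by 0.97 ± 0.24 and SVP by 0.79 ± 0.14. The nitrate transporter NRT2.1 rose by 5.49 ± 0.88, and the root patterning genes SCR (-1.28 ± 0.15) and SHR (-0.66 ± 0.14) fell. The heat shock factor HSFA6B fell (-4.17 ± 0.40), as did the abscisic acid genes HAI1 (-3.77 ± 1.11) and ABF3 (-1.64 ± 0.16). The cold regulator CBF3, raised at 15 min, was below its 0 min level at 4 h (-2.77 ± 0.49).

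Single growth and stress genes differed in their effect between 37 and 27 °C, while the thermomorphogenesis (camera adjusted p = 0.821) and flowering lists (0.225) were not called. FLC, a repressor of flowering, had a higher effect at 37 °C (difference 1.39 ± 0.33, log2, SE, adjusted p = 0.013), as did HY5 (1.07). PIF1, a relative of PIF4 (-1.36), and the expansin EXPA8 (-2.87) had lower ones. The antioxidant gene APX2 (6.34 ± 0.65) and the raffinose pathway gene GOLS2 (4.98) had the largest differences past the test among the other heat-response genes.

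Other splits of the same libraries asked how often an arbitrary division of them gives as many genes as the real one. Such splits cannot exclude chance differences between cultures, since no label says that the libraries came from separate ones. For 27C versus 17C over the 3 times 1 of 100 splits reached the real 315 genes, the real one itself. The highest other gave 17, and these splits were drawn without regard to time. With pairs parted 1 of 32 splits reached 315, and the highest other gave 0. For the 37C effect minus 17-to-27C effect 1 of 27 splits reached 3447, with 0 as the highest other. For unshifted 15 min versus 0 min 1 of 35 reached 367, with 51 as the highest other. For unshifted 4 h versus 0 min 1 of 35 reached 4829, with 3349 as the highest other. These splits moved labels between experiments, for which the fit had a term. Splits kept within experiments are too few to give a share under 0.05, so chance stays open for both. For the 22-to-27C effect minus 17-to-27C effect the real count was 0, which 27 of 27 splits reach by construction, so the splits tell nothing there. For 37C versus 17C over the 3 times and for 22C to 27C over the 3 times, where 1 of 10 splits each reached the real counts of 4476 and 59 and the highest other gave 0, the splits were too few to give a share under 0.05.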
